A study of Mus musculus with 16 samples.

How the data were processed

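The samples came from male C57BL/J mice aged 14 weeks, and the measurement was single-cell RNA sequencing of dissociated brain tissue. There were 16 libraries in 4 groups of 4 biological replicates: brains collected 1, 7 and 28 days after a closed-skull cortical impact (D1, D7 and D28) and brains without injury (No-TBI), where TBI stands for traumatic brain injury. Per the labels' protocols, the authors digested the tissue with collagenase D, DNase and papain, removed myelin debris with magnetic beads, fixed the cells in paraformaldehyde and hybridized each sample with its own probe barcode. The samples of 1 time point were then pooled and partitioned into droplets together. Per the submitters' processing notes, the authors processed the reads with Cell Ranger 7.1.0 and the mm10 genome build. The deposited values are UMI counts per gene and cell barcode in filtered matrices, without normalization; further filters of the authors are not given in the sources used here.

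The 16 matrices held 139694 barcodes and 19059 genes, of which 13 were mitochondrial, and the number of barcodes in each matrix equalled the number of called cells in the labels. A symbol carried by more than 1 identifier was left out of the gene lists, which concerned 6 symbols. Barcode sequences were available for 15 libraries, and each of these carried 1 probe barcode, the same for a given replicate number in every group. Libraries of the same group shared 8.65 to 24.2% of their droplet barcodes (median 20.8%, 21 pairs), and libraries of different groups 0.649 to 2.15% (median 1.54%, 84 pairs). Each group was therefore 1 pool, and an effect of the pool cannot be told apart from an effect of the group.

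Barcodes with fewer than 500 UMIs or 250 genes, or with over 10% mitochondrial UMIs, were removed, which left 138963. Doublet scores were computed per library with the Scrublet method in scanpy 1.11.5, and the highest-scoring barcodes were removed at 0.8% per 1000 barcodes, 11026 in all, which left 127937 cells. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours entered Leiden clustering at resolution 1 with igraph 0.11.9. Clusters were named from markers of 17 cell classes, and a named class is written X-like. The name was the class with the highest mean log2 ratio of its markers over their mean across clusters, with 10 CPM added. A cluster stayed unnamed when that score was under 0.3, when fewer than 3 of the markers reached 20 CPM, when another class reached 0.3 of its own usual level, or when its top 10 genes, detected in at least 0.25 of its cells, held more markers of another class. These limits were set after the clusters had been looked at over 3 rounds. Clusters 25 and 31, which looked mixed at first, were named microglia-like and endothelial-like under them.

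Counts were summed per class and library, and sums of at least 20 cells were kept. Genes were tested with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F test, Benjamini-Hochberg adjustment at 0.05) in 1 fit per class over all its samples. Standard errors were computed from the log2 change and the F value. CPM of named genes use TMM-scaled library sizes, while CPM of markers and of single libraries use plain sums. Cell shares were tested with edgeR's quasi-likelihood test on cell numbers, adjusted over the classes, and with a two-sided exact permutation test, for which 0.0286 is the smallest p that 4 against 4 libraries allow. The 33 fixed gene lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, for lists with at least 5 measured members, adjusted over the lists of a class and contrast. The samples entered 3 contrasts of an injured group with No-TBI, and endothelial-like cells and shares also D7 with D1 and D28 with D7. Cells were never used as replicates. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.

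The groups, contrasts, tests, markers, lists, alternatives and the rule for named genes were chosen before the data were examined. A named gene had an adjusted p under 0.05, a mean log2 CPM of at least 4, groups whose libraries did not overlap, and no other named class with a level over 5 times higher. Among these, the 10 largest rises and the 10 largest falls were named for each endothelial contrast with No-TBI, 5 of each for contrasts between time points and 4 of each in the other classes. Predicted genes with Gm or Rik names were passed over. For some lists, up to 4 members with the smallest p were named. The classes OPC-like, T/NK-like (D28 with D7) and neutrophil-like (D28 with D1) were chosen after the shares were seen. Where a group held no count of a gene, the fold is a bound from 3 counts over the whole group, and with 1 to 3 counts the level or the counts are given without a fold. Gene coordinates come from the GENCODE vM21 annotation of GRCm38, the build also called mm10, in which all 441 identifiers looked up were found.

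The gene test was checked on simulated counts with 200 changed genes per class, drawn for D1 with No-TBI. Changes of 1.5-fold, 2-fold and 4-fold were recovered in 80.2, 94.6 and 100% of cases for endothelial-like sums, and in 51.6, 84.3 and 100% for mural-like sums. The recovered shares were 94.5, 96.7 and 100% for microglia-like sums and 35.1, 66.7 and 100% for astrocyte-like sums. There were 9, 6, 14 and 10 false calls in these 4 classes. The alternatives were another normalization (median of ratios), the DESeq2 1.42.0 Wald test, no filter on low counts, a fit of the 2 groups compared, the replicate number as a block, counts thinned to the smallest library with at least 50 cells, doublets kept, a minimum of 1000 UMIs, Leiden resolution 2, genes over 5 times higher in another class left out, an estimated correlation or fry for lists, brain-resident cells as the denominator of shares, and leaving out each of the 16 libraries. Unnamed clusters added to their leading class were an alternative chosen after seeing the data.

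The replicate numbers of the labels equal the probe barcodes. In endothelial-like, mural-like, microglia-like and astrocyte-like cells, the deviations of same-numbered libraries from their group means were compared. Only for mural-like cells in D1 with No-TBI was the correlation over 0.1 in every pair (0.220 to 0.339, 4 of 4 pairs). With the number as a block this comparison gave 1867 genes in place of 1659. No cluster was oligodendrocyte-like, so the comparisons planned for that class were not made.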

Results

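The series asked how a severe blow to the head changes the cells of brain vessels over time. Single-cell RNA counts were collected from brains of mice 1, 7 and 28 days after a closed-skull cortical impact and from uninjured mice, with 4 libraries per group. The D1 libraries held 15213510, 26695641, 18517854 and 22622188 UMIs in replicates 1 to 4, and the D7 libraries 31461125, 23740040, 24145119 and 22492235. The D28 libraries held 20603851, 25734259, 36456042 and 34128385 UMIs, and the No-TBI libraries 26072013, 8269900, 49421674 and 16697721. Median UMIs per barcode were 1965.5 to 2303.5 at D1, 1372.5 to 1861 at D7, 2203 to 2374.5 at D28 and 3009 to 3688 in No-TBI. After filtering, 127937 cells remained. Values with ± are mean and SD over 4 libraries in CPM or percent, and log2 changes with ± carry their standard error. Every gene named as higher or lower below had 4 libraries of 1 group outside the range of the 4 of the other, except where members of a list are named. Largest and most refer to genes that met the criteria for named genes. Members of a list are counted after adjustment over all genes tested and, where that gives other counts, also adjusted over the list alone, so that a single pair of counts holds for both. As each group was processed as 1 pool, every difference between groups is also a difference between pools.

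Vessel, immune and most glial classes were recovered, and injury changed the balance between them within a day. Neutrophil-like cells, rare in uninjured tissue, flooded in at D1, were back near the uninjured level at D7 (34 cells) and rose again at D28. Lymphocytes accumulated at each time point. Microglia-like cells took a far smaller share at D1 and made up most cells at D28. Endothelial-like and mural-like cells took smaller shares at D7 and D28.

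At D1 compared with No-TBI, 10 of 12 classes changed share by edgeR's quasi-likelihood test (n = 4 per group). Neutrophil-like cells rose from 0.153 ± 0.0947 to 9.52 ± 2.67% (log2 ratio 5.89 ± 0.42, adjusted p = 6.3e-09). Monocyte/macrophage-like cells rose from 2.12 ± 0.0934 to 7.72 ± 1.06% (adjusted p = 2.7e-08) and dendritic-like cells from 0.142 ± 0.0286 to 1.92 ± 0.609% (adjusted p = 1e-08). Astrocyte-like cells rose from 4.03 ± 0.324 to 9.83 ± 3.38%, ependymal-like cells from 0.343 ± 0.14 to 1.12 ± 0.0989%, fibroblast-like cells from 0.243 ± 0.0559 to 0.781 ± 0.216% and T/NK-like cells from 0.266 ± 0.0494 to 0.822 ± 0.116%. Microglia-like cells fell from 42.9 ± 2.06 to 20.7 ± 1.34% (log2 ratio -1.05 ± 0.07, adjusted p = 5.9e-09) and OPC-like cells, the oligodendrocyte precursors, from 5.33 ± 0.268 to 1.03 ± 0.531% (log2 ratio -2.37 ± 0.30, adjusted p = 3.1e-06). Endothelial-like cells rose from 28.2 ± 0.842 to 31.6 ± 0.336% (adjusted p = 0.028). That rise did not pass with doublets kept (adjusted p = 0.102) or without D1 replicate 2 (0.0641), No-TBI replicate 1 (0.0695) or No-TBI replicate 4 (0.0723). Mural-like cells (adjusted p = 0.74) and neuroblast-like cells (adjusted p = 0.56) did not pass. In the 10 classes that passed, the libraries of the groups did not overlap, and the exact permutation test gave its smallest possible p of 0.0286.

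At D7, 9 of 12 classes differed from No-TBI. Dendritic-like cells stood at 1.91 ± 0.408% (log2 ratio 3.67 ± 0.28, adjusted p = 2.6e-08), T/NK-like cells at 1.49 ± 0.214% (2.48 ± 0.20, adjusted p = 3.1e-08) and fibroblast-like cells at 0.835 ± 0.257% (1.73 ± 0.28, adjusted p = 6.7e-05), with ependymal-like cells also higher. Neuroblast-like cells were higher by edgeR's test (adjusted p = 0.017), but their libraries overlapped (exact permutation p = 0.143), and they did not pass with a minimum of 1000 UMIs (adjusted p = 0.116) or without D7 replicate 4 (0.0574). Endothelial-like cells were lower at 21.3 ± 1.54% (log2 ratio -0.41 ± 0.06, adjusted p = 6.7e-05), mural-like cells at 8.28 ± 1.03%, OPC-like cells at 2.83 ± 0.732% and astrocyte-like cells at 2.62 ± 0.59%. Microglia-like, monocyte/macrophage-like and neutrophil-like cells did not pass (adjusted p = 0.2, 0.98 and 0.13). With a minimum of 1000 UMIs, microglia-like and monocyte/macrophage-like cells were higher (adjusted p = 0.00218 and 0.015) and neutrophil-like cells lower (0.00107). Microglia-like cells were also higher with unnamed clusters added (0.000734) and over brain-resident cells alone (0.0351). At D28, 8 of 12 classes differed. T/NK-like cells reached 2.61 ± 0.551% (log2 ratio 3.29 ± 0.20, adjusted p = 1.1e-09), microglia-like cells 55.1 ± 2.89% (0.36 ± 0.07, adjusted p = 0.00022) and neutrophil-like cells 1.64 ± 0.664% (3.36 ± 0.44, adjusted p = 7.2e-06), and dendritic-like and fibroblast-like cells were higher. Mural-like cells fell to 6.42 ± 0.377% (log2 ratio -0.86 ± 0.12, adjusted p = 1e-05), endothelial-like cells to 20.7 ± 0.587% (-0.45 ± 0.06, adjusted p = 1.4e-05) and OPC-like cells to 1.49 ± 0.231%. Shares depend on each other, and the dissociation and the myelin beads can set them. Clusters left unnamed by the naming limits held 3.52 ± 0.371% of cells in No-TBI, 2.42 ± 0.52% at D1, 10.1 ± 1.24% at D7 and 3.12 ± 0.29% at D28.

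**Figure D1:**
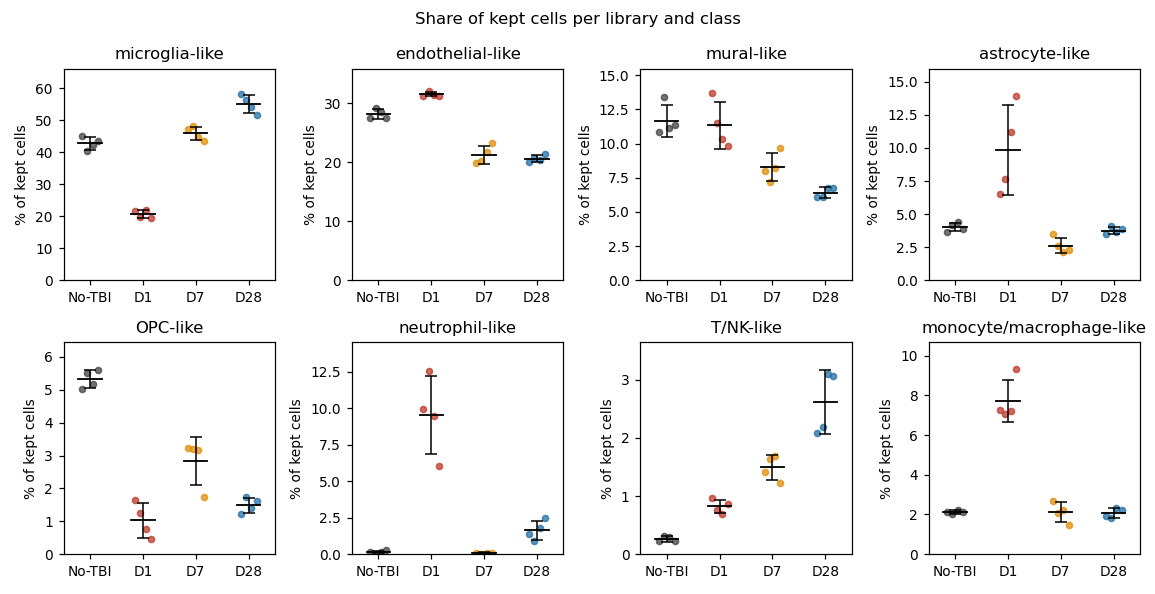
Shares of kept cells (percent, linear axis) for 8 cell classes in No-TBI, D1, D7 and D28, with each library as a point and the mean and SD of 4 libraries as a line and bar. Neutrophil-like cells average 9.52% at D1, 0.0767% at D7 and 1.64% at D28.

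In endothelial-like cells the tip-cell peptide apelin and placental growth factor, barely present in uninjured vessels, rose most within a day. The angiogenesis list as a whole did not pass (adjusted p = 0.551). The clock output factor Dbp and von Willebrand factor also rose, and the metallothionein Mt2, the chaperone Hspa1a and the mitochondrial mt-Co3 fell.

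In D1 with No-TBI, 2092 genes rose and 2275 fell of 10813 tested, 152 and 240 of them over 2-fold. For 3688 genes (34.1%) the libraries of the groups did not overlap, against 2.86% by chance. Apln (ENSMUSG00000037010, X 48025146-48034853 in GRCm38) rose from 5.13 ± 6.81 to 241 ± 70.1 CPM (log2 change 6.14 ± 0.35, adjusted p = 7.7e-11). Pgf rose from 1.68 ± 0.821 to 66.1 ± 20.7 CPM (log2 change 5.18 ± 0.38, adjusted p = 1.6e-09). The other large rises, as log2 changes, were the secretoglobin Scgb3a1 (3.15 ± 0.21), the clock output factor Dbp (1.99 ± 0.18), the growth factor binder Igfbp4 (1.90 ± 0.23), the matrix protease Adamts9 (1.21 ± 0.13), Reep1 (1.18 ± 0.11), the immunophilin Fkbp1a (1.17 ± 0.08), the actin-capping gene Capg (1.12 ± 0.07) and von Willebrand factor, Vwf (1.09 ± 0.09, from 171 ± 23.7 to 367 ± 36 CPM). The largest falls were the metallothionein Mt2 (-1.51 ± 0.10), the interferon-induced GTPase Tgtp1 (-1.35 ± 0.11), Lypd1 (-1.28 ± 0.16), the matrix gene Ltbp4 (-1.27 ± 0.08), mt-Co3 (-1.25 ± 0.07), Ywhaz (-1.23 ± 0.12), the chaperone Hspa1a (-1.22 ± 0.09), Fbln2 (-1.20 ± 0.13), the glucocorticoid-induced factor Zbtb16 (-1.19 ± 0.27) and the cell-cycle inhibitor Cdkn1c (-1.17 ± 0.12). The highest adjusted p among these 20 genes was 0.0015, for Zbtb16, by edgeR's test. Counts thinned to the smallest library gave 2026 genes in place of 4367. The mix of clusters differed too: cluster 18, led by Slc38a5 and Vwf, held 351 of 6167 cells of the class in No-TBI and 1035 of 8059 at D1, and cluster 8 held 2140 and 1300.

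Of 23 gene lists, 5 moved at D1 by camera. Immediate-early and heat-shock genes fell (adjusted p = 4.42e-08, adjusted p = 0.056 with an estimated correlation): 1 of 26 rose, 14 fell and 11 did not pass, and 1 and 15 adjusted over the list alone. Arterial and Notch genes fell (adjusted p = 0.00119, adjusted p = 0.446 with an estimated correlation), with 2 up and 13 down of 22, or 2 and 14 adjusted over the list alone. Nuclear-encoded oxidative phosphorylation genes rose (adjusted p = 0.0079, adjusted p = 0.126 with an estimated correlation), with 11 up and 2 down of 22, or 13 and 3 adjusted over the list alone. Interferon genes fell (adjusted p = 0.0147, adjusted p = 0.496 with an estimated correlation), with 3 up and 13 down of 27. Capillary genes fell (adjusted p = 0.0282, adjusted p = 0.496 with an estimated correlation), with 1 up and 7 down of 16.

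The other 18 lists did not pass at D1, with adjusted p from 0.123 to 0.867. In the angiogenesis and tip-cell list (adjusted p = 0.551) 12 genes rose, 10 fell and 7 of 29 did not pass, with 13 and 10 adjusted over the list alone. In the coagulation list (adjusted p = 0.123) 7 rose and 2 fell of 17. Of 24 genes of vascular tone and shear response (adjusted p = 0.123) 3 rose and 6 fell, or 3 and 7 adjusted over the list alone. Of 18 junction genes (adjusted p = 0.727) 5 rose and 5 fell. The tight junction gene Cldn5 rose by 0.37 ± 0.06. The list test and the mean (0.06) pointed up and the median (-0.02) down. Of 26 barrier transporter genes (adjusted p = 0.181) 5 rose and 10 fell. Within these sums, markers of microglia-like cells stood at 592 ± 98.9 CPM against 1296 ± 365 in No-TBI, and markers of monocyte/macrophage-like cells at 3609 ± 159 against 2498 ± 50.3.

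At D7 the endothelial picture was dominated by an interferon response. Nearly the whole interferon list rose (adjusted p = 0.0126 with an estimated correlation). The cholesterol synthesis list (0.0126) and the immediate-early and heat-shock list (0.0157) fell, several mitochondrial transcripts were lower, and the acute-phase gene lipocalin-2 had fallen most.

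In D7 with No-TBI, 1877 genes rose and 1910 fell of 10813, 178 and 84 of them over 2-fold, and 3543 genes (32.8%, 2.86% by chance) had groups that did not overlap. Lcn2 (ENSMUSG00000026822, chromosome 2 32384633-32388252) fell from 458 ± 38 to 25.9 ± 11 CPM (log2 change -4.14 ± 0.32, adjusted p = 2.6e-09). Irf7, which drives interferon genes, rose from 99.9 ± 7.97 to 306 ± 10.9 CPM (log2 change 1.63 ± 0.09, adjusted p = 2.2e-11), and Ifit3 from 63.4 ± 2.21 to 219 ± 31.9 CPM (log2 change 1.81 ± 0.10, adjusted p = 2.6e-11). The interferon-induced Ifit2 (2.30 ± 0.14), Ifit3b (1.98 ± 0.12) and Ifi44 (1.34 ± 0.10) were among the 10 largest rises of genes that met the criteria, with Pgf (2.42 ± 0.54), Dbp (1.55 ± 0.18), Scgb3a1 (1.49 ± 0.26), Lrrn3 (1.48 ± 0.12) and the adhesion receptor P-selectin, Selp (1.26 ± 0.42). Zbtb16 fell from 603 ± 15.9 to 137 ± 94.1 CPM (log2 change -2.13 ± 0.29). The other falls were Coro2a (-1.77 ± 0.17), the collagen hydroxylase P4ha2 (-1.70 ± 0.10), Map3k6 (-1.61 ± 0.08) and the mitochondrial mt-Atp8 (-1.61 ± 0.08), mt-Nd2 (-1.59 ± 0.08), mt-Cytb (-1.52 ± 0.09), mt-Nd3 (-1.47 ± 0.10) and mt-Nd4l (-1.40 ± 0.09). The highest adjusted p of these 20 genes was 0.025, for Selp, by edgeR's test. Thinned counts gave 1661 genes in place of 3787. Cluster 8 held 1042 of 9208 cells against 2140 of 6167 in No-TBI, cluster 14, with a median of 684 UMIs, 1539 against 233, and cluster 32, led by Ifit1 and Ifit3b, 213 against 7.

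Interferon genes rose as a list (camera, adjusted p = 3.11e-23, adjusted p = 0.0126 with an estimated correlation), with 26 of 27 members up, none down and 1 not passed. Immediate-early and heat-shock genes fell (adjusted p = 6.33e-09, adjusted p = 0.0157 with an estimated correlation), with none up and 16 down of 26, or 18 down adjusted over the list alone. Cholesterol synthesis genes fell (adjusted p = 4.03e-08, adjusted p = 0.0126 with an estimated correlation), with 1 up and 14 down of 20. Another class held over 5 times more of 11 of these 20. Antigen presentation genes rose (adjusted p = 3.85e-07, adjusted p = 0.0982 with an estimated correlation), with 12 up and none down of 17. The other 19 lists did not pass (adjusted p 0.0826 to 0.916). Of 18 junction genes (adjusted p = 0.916) 6 rose and 5 fell, with Cldn5 up (0.58 ± 0.06). The test of that list pointed down, its mean (0.03) and median (0.04) up. Of 26 transporter genes (adjusted p = 0.283) 13 rose and 6 fell, or 14 and 6 adjusted over the list alone. In these sums, markers of microglia-like cells stood at 1550 ± 164 CPM and of monocyte/macrophage-like cells at 2991 ± 149 against 2498 ± 50.3 in No-TBI. Markers of T/NK-like cells stood at 6.35 ± 2.05 against 1.95 ± 1.05 and of fibroblast-like cells at 44.3 ± 13.3 against 26.3 ± 5.18.

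At D28 the interferon response of the endothelium had subsided, yet many genes still differed from uninjured vessels. Lipocalin-2 was still low, the venular Ackr1 and the adhesion receptor Vcam1 were lower, and the immediate-early Egr1 and Fos were higher. Arterial and Notch genes, basement membrane genes and genes of caveolae were lower as lists with the preset correlation, with adjusted p = 0.249, 0.249 and 0.18 with an estimated correlation.

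In D28 with No-TBI, 1629 genes rose and 2022 fell of 10813, 97 and 66 of them over 2-fold, and 3640 genes (33.7%, 2.86% by chance) had groups that did not overlap. Lcn2 was still lower at 67.8 ± 17.2 CPM (log2 change -2.77 ± 0.27). The chemokine-binding Ackr1 of venules (-1.64 ± 0.45), Emp1 (-1.58 ± 0.13), the adhesion receptor Vcam1 (-1.43 ± 0.12, from 492 ± 68.8 to 182 ± 10.9 CPM), Fosl1 (-1.38 ± 0.19), Adamts9 (-1.37 ± 0.16), Gprc5a (-1.37 ± 0.19), the elastic fibre gene Fbln5 (-1.36 ± 0.23), Zfp52 (-1.32 ± 0.09) and the chaperone Hsph1 (-1.25 ± 0.09) fell. The largest rises were Lrrn3 (1.27 ± 0.12), Synpo2 (1.12 ± 0.09), Ifit2 (1.09 ± 0.15), Iqcn (1.06 ± 0.17), the immediate-early Egr1 (1.02 ± 0.21) and Fos (0.92 ± 0.17), the cold-induced Cirbp (0.96 ± 0.09), the kinase Map2k6 (0.95 ± 0.12), Plscr2 (0.89 ± 0.09) and Alox12 (0.87 ± 0.12). The highest adjusted p of these 20 genes was 0.0071, for Ackr1, by edgeR's test. Thinned counts gave 1537 genes in place of 3651. Cluster 8 held 1288 of 7717 cells against 2140 of 6167 in No-TBI.

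At D28, 5 lists passed and none of them passed with an estimated correlation. Arterial and Notch genes fell (adjusted p = 0.000399, adjusted p = 0.249 with an estimated correlation), with 1 up and 13 down of 22, or 14 down adjusted over the list alone. Cholesterol synthesis genes fell (adjusted p = 0.0038, adjusted p = 0.186 with an estimated correlation), with 2 up and 11 down of 20, or 2 and 13 over the list alone. Genes of caveolae fell (adjusted p = 0.0174, adjusted p = 0.18 with an estimated correlation), with 2 up and 6 down of 10. Basement membrane genes fell (adjusted p = 0.025, adjusted p = 0.249 with an estimated correlation), with 2 up and 10 down of 25, or 3 and 10 over the list alone. Antigen presentation genes rose (adjusted p = 0.0183, adjusted p = 0.415 with an estimated correlation), with 5 up and none down of 17, or 4 up over the list alone. Of the 18 lists that did not pass (adjusted p 0.0642 to 0.94), interferon genes (adjusted p = 0.125) had 9 up and 3 down of 27, junction genes (adjusted p = 0.19) 3 up and 6 down of 18 (4 and 8 over the list alone), with Cldn5 up (0.43 ± 0.06), and transporter genes (adjusted p = 0.589) 6 up and 6 down of 26 (9 and 6 over the list alone). In the immediate-early and heat-shock list (adjusted p = 0.565) 10 rose and 10 fell, or 11 and 10 over the list alone. Its median (0.11) was above 0 and its mean (-0.02) below. In these sums, markers of microglia-like cells stood at 1980 ± 291 CPM against 1296 ± 365 in No-TBI, of mural-like cells at 472 ± 82.6 against 318 ± 62.4 and of monocyte/macrophage-like cells at 2651 ± 70.3 against 2498 ± 50.3.

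**Figure D2:**
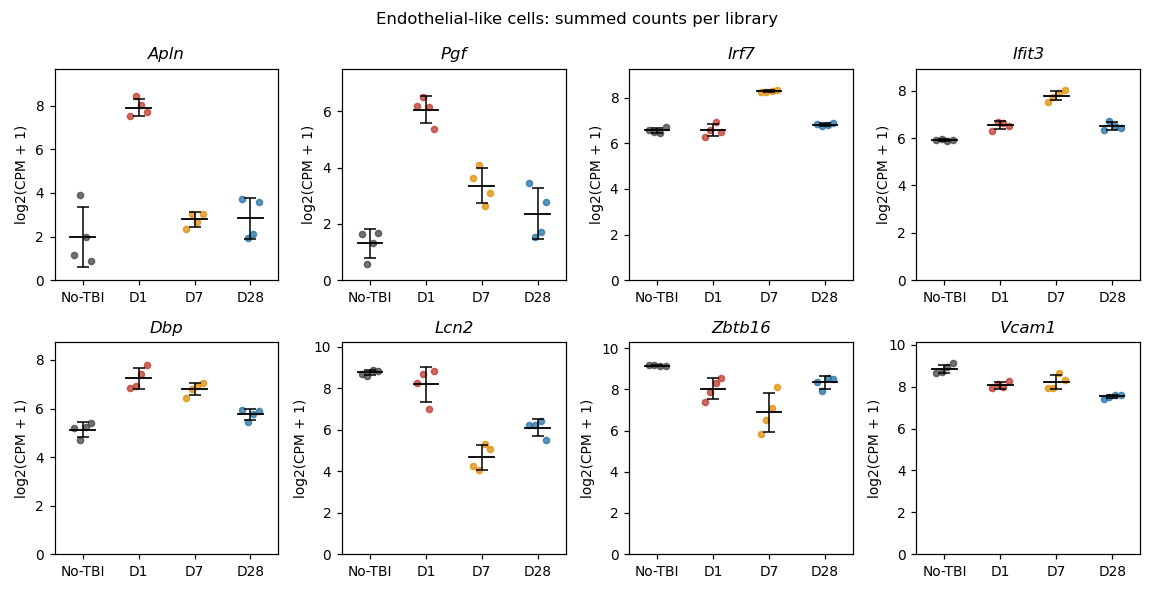
Levels of 8 genes in endothelial-like sums, as log2(CPM + 1), with each library as a point and the mean and SD of 4 libraries per group as a line and bar. Apln and Pgf stand highest at D1, Irf7 and Ifit3 at D7, and Lcn2 lowest at D7.

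The direct contrasts between time points ask how endothelial-like cells differed from one time point to the next. From D1 to D7 Apln and Pgf fell back and the interferon list rose (adjusted p = 0.00533 with an estimated correlation). From D7 to D28 the interferon list fell (0.00339), and the immediate-early and heat-shock list (0.0276) and the shear-induced Klf2 rose. The vascular tone and shear list did not pass (adjusted p = 0.419).

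In D7 with D1, 1829 genes rose and 1619 fell, 310 and 71 of them over 2-fold, and 3038 (28.1%, 2.86% by chance) had groups that did not overlap. The GTPases Iigp1 (2.20 ± 0.12) and Tgtp1 (2.01 ± 0.11), Ifit3b (1.81 ± 0.12), Ifit2 (1.74 ± 0.13) and Irf7 (1.74 ± 0.09) rose most. Apln (-5.34 ± 0.33), Lcn2 (-3.58 ± 0.32), Pgf (-2.76 ± 0.29), Igfbp3 (-1.82 ± 0.19) and Scgb3a1 (-1.66 ± 0.18) fell most, all 10 with an adjusted p of at most 5e-07 by edgeR's test. Interferon genes rose in 27 of 27 cases (camera, adjusted p = 1.52e-33, adjusted p = 0.00533 with an estimated correlation), and cholesterol genes fell in 15 of 20 (adjusted p = 5.77e-08, adjusted p = 0.00864 with an estimated correlation). Antigen presentation genes rose in 13 of 17 cases (adjusted p = 0.0779 with an estimated correlation). Another 3 lists rose with the preset correlation but not with an estimated one: barrier transporters (adjusted p = 0.426 with an estimated correlation), capillary genes (0.391) and Wnt/beta-catenin barrier genes (0.311). Thinned counts gave 1388 genes in place of 3448.

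In D28 with D7, 649 genes rose and 1031 fell, 48 and 107 of them over 2-fold, and 2226 (20.6%, 2.86% by chance) had groups that did not overlap. Egr1 (1.66 ± 0.21), Fos (1.41 ± 0.17), Klf2 (1.40 ± 0.12), Lcn2 (1.37 ± 0.36) and Btg2 (1.29 ± 0.16) rose most, and Selp (-2.54 ± 0.48), Igfbp4 (-1.67 ± 0.26), Emp1 (-1.51 ± 0.13), Ifit3b (-1.47 ± 0.12) and Irf7 (-1.47 ± 0.08) fell most, with adjusted p up to 0.011 (Lcn2, edgeR's test). Interferon genes fell in 27 of 27 cases (camera, adjusted p = 2.06e-37, adjusted p = 0.00339 with an estimated correlation). Cholesterol genes rose (10 up and none down of 20, 14 and 1 over the list alone, adjusted p = 0.0119 with an estimated correlation), as did immediate-early and heat-shock genes (12 up and 3 down of 26, adjusted p = 0.0276 with an estimated correlation). Basement membrane genes fell (2 up and 14 down of 25, 3 and 15 over the list alone, adjusted p = 0.0119 with an estimated correlation). Another 6 lists fell with the preset correlation but not with an estimated one: antigen presentation (adjusted p = 0.138 with an estimated correlation), leukocyte adhesion and chemokines (0.19), angiogenesis (0.19), coagulation (0.113), oxidative stress and iron (0.138) and endothelial-to-mesenchymal transition (0.113). Thinned counts gave 636 genes in place of 1680.

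Mural-like cells, the pericytes and smooth muscle cells of the vessel wall, raised the cytokines Il11 and Lif at D1 and D7. The interferon list (adjusted p = 0.00675 and 0.000224 with an estimated correlation) and the fibrotic matrix list (0.00164 and 0.0017) rose at both. The contractile and pericyte lists did not pass at either. At D28, 417 genes still differed.

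In D1 with No-TBI, 798 mural genes rose and 861 fell of 9993 tested, and 1870 (18.7%, 2.86% by chance) had groups that did not overlap. The cytokines Il11 (5.17 ± 0.47) and Lif (3.12 ± 0.31), Lgals1 (2.12 ± 0.18) and the collagen cross-linker Loxl2 (2.01 ± 0.19) rose most, and the clock gene Npas2 (-1.78 ± 0.29), Khk (-1.48 ± 0.30), Eps8l1 (-1.46 ± 0.28) and Zbtb16 (-1.45 ± 0.20) fell most (adjusted p up to 0.0014, edgeR's test). Interferon genes rose (14 up and none down of 24, 18 over the list alone; camera, adjusted p = 6.89e-14, adjusted p = 0.00675 with an estimated correlation). Fibrotic matrix genes rose (14 up and 1 down of 16; adjusted p = 3.44e-11, adjusted p = 0.00164 with an estimated correlation), although another class held over 5 times more of 14 of the 16, and fibroblast markers in these sums rose from 1040 ± 97.9 to 1548 ± 172 CPM. Immediate-early and heat-shock genes fell (2 up and 11 down of 26, 2 and 14 over the list alone, adjusted p = 0.0282 with an estimated correlation), oxidative phosphorylation genes rose (5 up and none down of 22, 8 up over the list alone, adjusted p = 0.0261 with an estimated correlation), and cholesterol genes rose (8 up and none down of 20; adjusted p = 0.000196, adjusted p = 0.0569 with an estimated correlation). The pericyte (4 up and 1 down of 16, 7 and 1 over the list alone, adjusted p = 0.0839) and contractile lists (1 up and none down of 16, adjusted p = 0.846) did not pass. Microglial markers stood at 1284 ± 907 CPM against 5656 ± 2844 in No-TBI, and monocyte/macrophage markers at 1438 ± 165 against 904 ± 177. Thinned counts gave 989 genes, and doublets kept gave 2501, in place of 1659.

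In D7 with No-TBI, 667 mural genes rose and 463 fell, and 1569 (15.7%, 2.86% by chance) had groups that did not overlap. Il11 (4.00 ± 0.55), Lif (2.63 ± 0.34), Ifit3 (2.40 ± 0.22) and Il6 (2.35 ± 0.32) rose, and Zbtb16 (from 175 ± 22.1 to 42.4 ± 25.2 CPM), mt-Nd2 (-1.71 ± 0.11), mt-Cytb (-1.67 ± 0.14) and mt-Atp8 (-1.66 ± 0.13) fell, with adjusted p up to 3.9e-05 (edgeR's test). Interferon genes rose in 23 of 24 cases (camera, adjusted p = 5.32e-35, adjusted p = 0.000224 with an estimated correlation), fibrotic matrix genes in 11 of 16 (12 over the list alone; adjusted p = 0.0017 with an estimated correlation) and antigen presentation genes in 6 of 14 (10 over the list alone; adjusted p = 0.0177 with an estimated correlation). Fibroblast markers in these sums stood at 1547 ± 196 CPM against 1040 ± 97.9 in No-TBI, and monocyte/macrophage markers at 1557 ± 103 against 904 ± 177. Cholesterol genes fell (7 down of 20, 2 up and 9 down over the list alone; adjusted p = 0.000411, adjusted p = 0.0874 with an estimated correlation), as did immediate-early and heat-shock genes (3 up and 8 down of 26, 3 and 12 over the list alone; adjusted p = 0.00203, adjusted p = 0.203 with an estimated correlation). Without D7 replicate 1 the comparison gave 693 genes in place of 1130, thinned counts gave 651 and doublets kept gave 1719.

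In D28 with No-TBI, 172 mural genes rose and 245 fell, and 1184 (11.8%, 2.86% by chance) had groups that did not overlap. The signalling regulator Rgs16 (1.28 ± 0.21), Ppm1n (1.19 ± 0.30), N6amt1 (1.14 ± 0.23) and Trim68 (0.94 ± 0.24) rose, and the chaperones Fkbp4 (-1.26 ± 0.17) and Hspa1a (-1.22 ± 0.10), P4ha1 (-1.23 ± 0.09) and Dusp18 (-1.22 ± 0.21) fell, with adjusted p up to 0.03 (edgeR's test). With camera 8 of 12 lists passed and none did with an estimated correlation (adjusted p 0.0556 to 0.285). Immediate-early and heat-shock genes (2 up and 11 down of 26, 3 and 14 over the list alone), cholesterol genes (2 down of 20, 8 over the list alone) and cell-cycle genes (none of 7 passed) were lower. Contractile genes (1 up and 1 down of 16, 3 and 1 over the list alone), fibrotic matrix (5 up and 1 down of 16, 7 and 1 over the list alone), antigen presentation (1 up of 14, 2 over the list alone), oxidative phosphorylation (none of 22 passed, 3 over the list alone) and interferon genes (1 up of 24, 3 over the list alone) were higher. Markers of monocyte/macrophage-like cells in these sums stood at 1340 ± 95.8 CPM against 904 ± 177 in No-TBI, and of fibroblast-like cells at 1228 ± 62.6 against 1040 ± 97.9. The count of 417 genes was 265, 264, 271 and 231 without D28 replicates 1 to 4 and 262 without No-TBI replicate 4. It was 225 with thinned counts, 983 with doublets kept and 1185 with unnamed clusters added.

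In microglia-like cells more genes passed than in the other classes at each time point, although simulated changes were also recovered most often there. The scavenger receptor Msr1 and the lipase Lpl led the rises at D1, and the disease-associated list rose at D7 and D28 (adjusted p = 0.0324 and 0.0246 with an estimated correlation). Markers of monocyte/macrophage-like cells in these sums stood at 172 ± 3.83 CPM in No-TBI, 418 ± 60.8 at D1, 1292 ± 149 at D7 and 1596 ± 183 at D28.

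In D1 with No-TBI, 4098 microglial genes rose and 4028 fell of 11516 (1113 and 1060 over 2-fold), and 6888 (59.8%, 2.86% by chance) had groups that did not overlap. Cluster 24, with Lpl, Cd72 and Msr1 among its top genes, held 1478 of 5237 cells of the class at D1 and 3 in No-TBI. It was named with a score of 0.401, near the limit of 0.3, and none of its top 10 genes was a microglial marker. The scavenger receptor Msr1 (8.02 ± 0.21), the lipase Lpl (5.76 ± 0.15), osteopontin, Spp1 (5.15 ± 0.41), and the elastase Mmp12 (5.07 ± 0.28) rose most, and Eps8l1 (-3.36 ± 0.24), Tnfsf18 (-3.04 ± 0.17), Upk1b (-2.92 ± 0.14) and Klhl38 (-2.71 ± 0.13) fell most (adjusted p up to 2.4e-10, edgeR's test). Oxidative phosphorylation genes rose (21 of 22; camera, adjusted p = 8.19e-09, adjusted p = 0.0292 with an estimated correlation) and immediate-early and heat-shock genes fell (2 up and 23 down of 26, adjusted p = 0.0292 with an estimated correlation). Homeostatic genes fell (1 up and 15 down of 16; adjusted p = 2.3e-07, adjusted p = 0.217 with an estimated correlation). Disease-associated genes rose (19 up and 2 down of 23; adjusted p = 7.82e-05, adjusted p = 0.38 with an estimated correlation), as did cell-cycle genes (14 up and 4 down of 23; adjusted p = 0.0416, adjusted p = 0.606 with an estimated correlation).

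In D7 with No-TBI, 3718 microglial genes rose and 3592 fell, and 6562 (57%, 2.86% by chance) had groups that did not overlap. Apoc1, with 3 counts in all of No-TBI, stood at 88.5 ± 30.9 CPM. Igf1 (7.87 ± 0.35), Spp1 (7.72 ± 0.41) and Ifi27l2a (6.98 ± 0.12) rose most, and Bank1 (-2.63 ± 0.14), Gpr165 (-2.34 ± 0.12) and the glucocorticoid-induced Tsc22d3 (-2.14 ± 0.05) and Fkbp5 (-2.14 ± 0.07) fell most (adjusted p up to 8.9e-12, edgeR's test). Disease-associated genes rose in 23 of 23 cases (camera, adjusted p = 4.06e-18, adjusted p = 0.0324 with an estimated correlation). Interferon genes rose in 25 of 27 cases and antigen presentation genes in 16 of 19 (adjusted p = 0.0324 and 0.0269 with an estimated correlation). Oxidative phosphorylation (17 up of 22, 18 over the list alone) and glycolysis genes (15 up and 3 down of 22) rose and immediate-early and heat-shock genes fell (2 up and 21 down of 26), all also with an estimated correlation. Homeostatic genes fell (2 up and 14 down of 16, adjusted p = 0.154 with an estimated correlation), and cell-cycle genes (18 up and 2 down of 23, adjusted p = 0.219 with an estimated correlation) and cytokine genes (14 up and 4 down of 20, adjusted p = 0.226 with an estimated correlation) rose. Cluster 4 held 7192 of 19844 cells of the class against 27 of 9446 in No-TBI, and cluster 6 held 2360 against 16. Thinned counts gave 4176 genes in place of 7310.

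In D28 with No-TBI, 3090 microglial genes rose and 2988 fell, and 5806 (50.4%, 2.86% by chance) had groups that did not overlap. Apoc1 stood at 153 ± 55.7 CPM. Igf1 (7.72 ± 0.36), Apoe (6.89 ± 0.15) and Spp1 (6.69 ± 0.41) rose most, and Edn1 (-2.10 ± 0.21), Tnfsf18 (-2.06 ± 0.12), Fosl1 (-1.95 ± 0.15) and Sphk1 (-1.88 ± 0.19) fell most (adjusted p up to 3.6e-08, edgeR's test). Disease-associated genes rose in 23 of 23 cases (camera, adjusted p = 1.38e-22, adjusted p = 0.0246 with an estimated correlation), antigen presentation genes in 16 of 19, and glycolysis genes with 13 up and 2 down of 22, the latter pair also with an estimated correlation. Interferon (24 up and 1 down of 27, adjusted p = 0.111 with an estimated correlation), oxidative phosphorylation (14 up and 1 down of 22, 15 and 1 over the list alone, 0.109) and cholesterol genes (12 up and 2 down of 20, 0.202) rose, and homeostatic (1 up and 12 down of 16, 0.164) and immediate-early and heat-shock genes (4 up and 14 down of 26, 5 and 14 over the list alone, 0.0877) fell. Cluster 6 held 4885 of 20400 cells of the class against 16 of 9446 in No-TBI, and cluster 17, led by Apoc1, Igf1 and Spp1 among others and named with a score of 0.575, held 1653 against 1. Thinned counts gave 3120 genes in place of 6078.

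In astrocyte-like cells the cholesterol synthesis list fell at D1 and D7 (adjusted p = 7.48e-05 and 0.000429 with an estimated correlation), and the interferon list rose at D7 (0.0403). The reactive list rose at both with the preset correlation (adjusted p = 0.0643 and 0.0527 with an estimated correlation).

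In D1 with No-TBI, 863 astrocyte genes rose and 937 fell of 9275, and 2019 (21.8%, 2.86% by chance) had groups that did not overlap. Steap4, without a count in No-TBI, was at least 65.4-fold higher. Ptx3 (492 ± 222 CPM, 1 count in No-TBI), Lcn2 (739 ± 182 CPM, 2 counts in No-TBI) and the transglutaminase Tgm1 (172 ± 70.4 CPM, 3 counts in No-TBI) rose, and the mevalonate enzyme Mvd (-2.77 ± 0.20), Map3k19 (-2.56 ± 0.28), Eps8l1 (-2.43 ± 0.40) and mt-Nd6 (-2.36 ± 0.16) fell (adjusted p up to 6e-05, edgeR's test). Cholesterol genes fell in 18 of 20 cases (camera, adjusted p = 1.03e-30, adjusted p = 7.48e-05 with an estimated correlation). Reactive genes rose in 21 of 24 cases (22 over the list alone; adjusted p = 4.73e-17, adjusted p = 0.0643 with an estimated correlation), among them Serpina3n (5.82 ± 0.34), Osmr (4.24 ± 0.30) and Gfap (2.98 ± 0.27). Oxidative stress (8 up of 17, 11 over the list alone, adjusted p = 0.0643 with an estimated correlation), interferon (9 up of 22, 10 over the list alone, 0.288), oxidative phosphorylation (4 up of 21, 0.288) and p53 genes (5 up and 2 down of 18, 7 and 2 over the list alone, 0.295) rose, and immediate-early and heat-shock genes fell (2 up and 11 down of 26, 3 and 14 over the list alone, 0.295). Microglial markers in these sums fell from 4266 ± 1150 to 1097 ± 663 CPM. Thinned counts gave 163 genes in place of 1800.

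In D7 with No-TBI, 1948 astrocyte genes rose and 1796 fell (947 and 556 over 2-fold), and 3136 (33.8%, 2.86% by chance) had groups that did not overlap. The hyaluronan synthase Has2 and Steap4, without counts in No-TBI, were at least 45.5-fold and 25.1-fold higher. Ptx3 (220 ± 128 CPM) and Il6 (211 ± 113 CPM), each with 1 count in No-TBI, rose, and Zbtb16 (-3.91 ± 0.22), Etnppl (-3.05 ± 0.22), Sycp2 (-3.02 ± 0.40) and Sult1a1 (-2.75 ± 0.35) fell (adjusted p up to 0.00017, edgeR's test). Cholesterol genes fell in 20 of 20 cases (camera, adjusted p = 7.1e-22, adjusted p = 0.000429 with an estimated correlation). Interferon genes rose in 22 of 22, antigen presentation genes in 11 of 11 and oxidative stress genes in 14 of 17 cases, each with an adjusted p of 0.0403 with an estimated correlation. Reactive genes rose in 23 of 24 cases (24 over the list alone; adjusted p = 6.11e-13, adjusted p = 0.0527 with an estimated correlation). Immediate-early and heat-shock (20 up of 26, 20 up and 2 down over the list alone, adjusted p = 0.108 with an estimated correlation), p53 (13 up of 18, 0.0527) and oxidative phosphorylation genes (7 up of 21, 0.261) rose. Homeostatic genes fell (3 up and 13 down of 19, adjusted p = 0.108 with an estimated correlation). In these sums markers of OPC-like cells stood at 931 ± 220 CPM against 379 ± 46.9 in No-TBI, of oligodendrocytes at 387 ± 56.1 against 111 ± 28.3 and of monocyte/macrophage-like cells at 263 ± 71.4 against 80.3 ± 47.1. Cluster 21 held 525 of 1141 cells of the class against 197 of 894. Thinned counts gave 469 genes in place of 3744.

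In D28 with No-TBI, 65 astrocyte genes rose and 93 fell, and 816 (8.8%, 2.86% by chance) had groups that did not overlap. Serpina3n (3.03 ± 0.39), Vim (2.16 ± 0.33) and Osmr (1.60 ± 0.40) rose. Lcn2 stood at 62.8 ± 116 CPM against 2 counts in No-TBI (adjusted p = 0.046, edgeR's test), with 242 CPM in D28 replicate 4. The mitochondrial mt-Nd6 (-1.85 ± 0.17), mt-Nd5 (-1.72 ± 0.12), mt-Cytb (-1.67 ± 0.12) and mt-Nd2 (-1.66 ± 0.12) fell. Reactive genes rose (7 up of 24, 13 over the list alone; camera, adjusted p = 0.000125, adjusted p = 0.556 with an estimated correlation), as did oxidative phosphorylation genes (1 up of 21; adjusted p = 0.000451, adjusted p = 0.556 with an estimated correlation). The immediate-early and heat-shock list fell (none of 26 passed, 3 down over the list alone; adjusted p = 0.0414, adjusted p = 0.556 with an estimated correlation), and without No-TBI replicate 3 the direction turned (adjusted p = 0.942). The count of 158 genes was 86 without D28 replicate 2, 86 without No-TBI replicate 1 and 79 without No-TBI replicate 3. It was 15 with thinned counts and 277 without the filter on low counts.

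In OPC-like cells the complement gene C4b rose at every time point, and the interferon list rose at D7 (adjusted p = 0.00291 with an estimated correlation). In D1 with No-TBI, 1018 genes rose and 714 fell of 9246, and 1909 (20.6%, 2.86% by chance) had groups that did not overlap. Lpl (5.78 ± 0.44) and Tnfsf9 (2.88 ± 0.35), both top genes of microglia-like cluster 24, C4b (3.47 ± 0.21) and Serpina3n (3.19 ± 0.22) rose. Plekhf1 (-2.42 ± 0.78), Gsg1l (-2.32 ± 0.52), Fndc5 (-2.16 ± 0.47) and Zbtb16 (-2.04 ± 0.19) fell (adjusted p up to 0.032 for all, edgeR's test). Oxidative stress (9 up of 16, 10 up and 1 down over the list alone) and glycolysis genes (7 up and 2 down of 18, 8 and 2 over the list alone) rose (camera, adjusted p = 0.0419 and 0.0489 with an estimated correlation). Cholesterol (12 up of 20, 13 over the list alone), interferon (8 up of 18, 10 over the list alone) and antigen presentation genes (5 up of 10, 6 over the list alone) rose with the preset correlation and had an adjusted p of 0.0948 with an estimated correlation. In D7 with No-TBI, 473 genes rose and 505 fell, and 1559 (16.9%) had groups that did not overlap. Usp18 (3.73 ± 0.43), Rtp4 (3.48 ± 0.31), C4b (3.21 ± 0.19) and Ddx60 (3.16 ± 0.44) rose, and Zbtb16 (-2.01 ± 0.15), Fkbp5 (-1.61 ± 0.20), Agmo (-1.43 ± 0.28) and Rreb1 (-1.42 ± 0.35) fell. Interferon (16 up of 18, 17 over the list alone) and oxidative phosphorylation genes (5 up of 21) rose (adjusted p = 0.00291 and 0.0478 with an estimated correlation). With the preset correlation, cholesterol (7 up of 20, 9 over the list alone; 0.103 with an estimated correlation), antigen presentation (4 up of 10, 7 over the list alone; 0.0827) and cell-cycle genes (2 up of 16; 0.196) also rose and immediate-early and heat-shock genes fell (1 up and 10 down of 26, 1 and 11 over the list alone; 0.103). In D28 with No-TBI, 126 genes rose and 117 fell, and 1171 (12.7%) had groups that did not overlap. C4b (3.13 ± 0.20), Gap43 (2.39 ± 0.21), Rtp4 (2.27 ± 0.38) and S100a2 (1.72 ± 0.37) rose, and Adm (-1.64 ± 0.29), Msmo1 (-1.22 ± 0.14), mt-Nd6 (-1.22 ± 0.17) and mt-Cytb (-1.11 ± 0.10) fell. Cholesterol (3 down of 20, 8 over the list alone) and immediate-early and heat-shock genes (5 down of 26, 1 up and 9 down over the list alone) fell and cell-cycle (1 up of 16, 4 over the list alone), interferon (2 up of 18) and antigen presentation genes (1 up of 10, 2 over the list alone) rose, none of them with an estimated correlation (adjusted p 0.186 to 0.283). The counts of 1732, 978 and 243 genes were 1027 without D1 replicate 2, 631 without D7 replicate 3, and 125 and 160 without D28 replicates 2 and 3. They were 195, 81 and 20 with thinned counts. With doublets kept D7 gave 1564 and D28 470, and D28 gave 486 with 2 groups in the fit and 413 with genes over 5 times higher in another class left out.

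In T/NK-like cells cell-cycle transcripts were lower at D28 than at D7 (adjusted p = 0.00598 with an estimated correlation). Of 7302 genes, 136 rose and 225 fell, and 938 (12.8%, 2.86% by chance) had groups that did not overlap. Il17rb (2.86 ± 0.55), the interleukin-33 receptor Il1rl1 (2.50 ± 0.37), Trbv29 (2.43 ± 0.29) and Il13 (2.10 ± 0.41) rose, and Tff1, without a count at D7, was at least 8.26-fold higher. The mitotic Nusap1 (-4.36 ± 0.49) and Spc24 (-4.19 ± 0.58), Birc5 (3 counts at D28), Cenpm (2 counts at D28) and Hist1h3c (at least 14.5-fold lower) fell (adjusted p up to 0.019, edgeR's test). Cell-cycle genes fell in 19 of 19 cases (camera, adjusted p = 3.51e-37, adjusted p = 0.00598 with an estimated correlation). Interferon genes fell in 13 of 25 cases (19 over the list alone), and oxidative phosphorylation genes were lower with none of 21 passing (2 over the list alone; adjusted p = 0.0106 and 0.0149 with an estimated correlation). The immediate-early and heat-shock list rose (5 up and 3 down of 26, 10 and 6 over the list alone; adjusted p = 0.0349, adjusted p = 0.314 with an estimated correlation). The count of 361 genes was 216 without D7 replicate 1, 227 without D7 replicate 3 and 199 without D28 replicate 3. It was 4 with thinned counts, 216 with the DESeq2 Wald test and 570 without the filter on low counts.

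Neutrophil-like cells of D28 differed from those of D1 in 670 genes. Of 4704 genes, 369 rose and 301 fell, and 894 (19%, 2.86% by chance) had groups that did not overlap. Vnn3 (2.30 ± 0.40), Tecpr1 (2.26 ± 0.31), Unc13d (2.12 ± 0.34), Ugt1a10 (2.10 ± 0.51) and the interleukin Il1f9 (2.01 ± 0.15) rose. Chil3 (-3.05 ± 0.42) and Ccdc80 (-2.87 ± 0.45) fell, as did Mmp19 (314 ± 99.7 CPM at D1, 2 counts at D28), Adamtsl4 (65 ± 17.3 CPM at D1, 3 counts at D28) and the nitric oxide synthase Nos2 (36.8 ± 6.37 CPM at D1, 2 counts at D28), with adjusted p up to 0.0089 (edgeR's test). Immediate-early and heat-shock (7 up and 2 down of 22, 10 and 2 over the list alone), antigen presentation (4 up of 13) and oxidative stress genes (6 up and 1 down of 16, 8 and 4 over the list alone) rose with camera, but not with an estimated correlation (adjusted p = 0.398, 0.143 and 0.143). The count of 670 genes was 445 without D28 replicate 4. It was 22 with thinned counts, 1018 with doublets kept and 334 with a minimum of 1000 UMIs.

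Transcripts of the mitochondrial genome took a smaller share of UMIs in most classes after injury. In endothelial-like cells they made up 1.36 ± 0.0863% in No-TBI, 0.747 ± 0.0393% at D1, 0.607 ± 0.0849% at D7 and 0.765 ± 0.0161% at D28. Astrocyte-like cells had 2.12 ± 0.131% in No-TBI and 0.77 ± 0.0386, 0.8 ± 0.184 and 0.819 ± 0.056% after injury. Microglia-like cells had 1.83 ± 0.0878% in No-TBI, 1.79 ± 0.0977% at D1, 0.916 ± 0.0719% at D7 and 1.03 ± 0.0141% at D28. These shares are values without a test, and the falls of single mitochondrial genes are those given above.

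**Figure D3:**
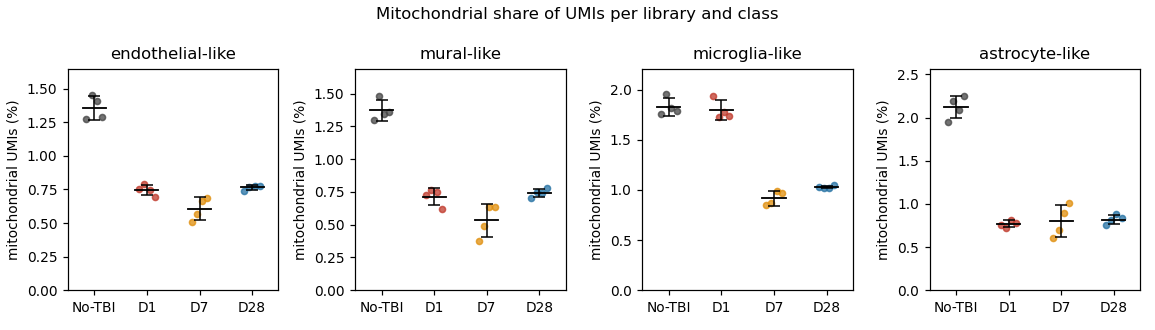
Share of UMIs from the 13 mitochondrial genes (percent, linear axis) in 4 cell classes, with each library as a point and the mean and SD of 4 libraries per group as a line and bar. Microglia-like cells at D1 lie near their No-TBI level, while endothelial-like cells at D1 lie below theirs.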

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

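Of the tests below, those of depth for the clock genes, of the number of mitochondria and of a step shared by a pool were chosen only after the results were seen. Results are given here when 1 library lay far from the other 3 of its group by Dixon's criterion, when the direct contrast of time points in endothelial-like cells or in shares passed, or when cells outside the compared classes were more frequent after injury than in No-TBI. Gene lists were not screened in this way.

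Clock genes moved at D1 in directions that differed between cell classes. In endothelial-like cells Dbp rose. Clock outputs were compared with Arntl, Clock, Nfil3 and Cry1 by median. The difference was 1.05 in endothelial-like, 0.42 in mural-like, -1.01 in microglia-like and -1.15 in astrocyte-like cells (log2, SE 0.256 for the last). The opposite signs argue against 1 shift in the time of day at harvest that acts alike in all 4 classes. Harvest times are not given. Dbp rose by 1.95 (log2) after thinning and 1.99 with all counts, but thinning keeps expected ratios and cannot test depth. A response of the clock to injury that differs between classes may explain the pattern and was not tested.

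Mitochondrial transcripts fell in the injured groups. Fewer mitochondria per cell might lower nuclear-encoded respiratory genes too. The lowest of the 12 medians of that list over 4 classes and 3 time points was 0.0563 (log2). These levels do not count mitochondria, so this stays open. A step shared by a whole pool, such as the dissociation or fixation of that day, might lower mitochondrial transcripts in all classes of a pool. The ratio to No-TBI in microglia-like cells at D1 was 0.982, against 0.928 in neuroblast-like, 0.916 in OPC-like and 0.55 in endothelial-like cells of the same pool, but classes may react differently to such a step, and group and pool cannot be told apart. A biological fall of mitochondrial transcription after injury also stays open.

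Neutrophil-like cells were more frequent at D28 than at D7 (log2 ratio 4.37 ± 0.42, adjusted p = 5.6e-07, edgeR's quasi-likelihood test). Barcodes carried over from the D1 pool are unlikely to be the source: 7 of 633 D28 neutrophil-like barcodes (1.11%) were also called at D1 with the same probe barcode, against 0.982% of other cells. More blood left in the D28 tissue stays open, since haemoglobin stood at 18.3 ± 18.4 CPM of all UMIs at D28 and 4.86 ± 5.92 at D7, a difference within the spread of libraries. No-TBI had 24.9 ± 23.3 CPM with 0.153% neutrophil-like cells and D1 13.7 ± 15.9 with 9.52%, which speaks against blood as the whole source, but these spreads overlap too. A late return of neutrophils after injury may explain the rise and was not tested further.

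In 32 of 422 groups of 4 libraries tested, 1 library lay far from the others, where chance gives about 21.1. No-TBI replicate 2, the library with the fewest cells, held 9 of them, D1 replicate 4 and D7 replicate 4 held 4 each and No-TBI replicate 3 held 3. None of 20 quality measures, 5 of 52 shares and 27 of 350 gene levels were affected. The shares were OPC-like cells in D7 replicate 4 (1.73%), neuroblast-like cells in D7 replicate 1 (0.923%), and in D1 replicate 4 dendritic-like cells (2.83%), monocyte/macrophage-like cells (9.30%) and unnamed cells (3.20%). In endothelial-like cells, No-TBI replicate 2 stood apart for Apln (14.2 CPM), Fbln5 (127) and Lrrn3 (38.0). No-TBI replicates 1, 3 and 4 did so for Alox12 (18.5), mt-Nd3 (365) and Ywhaz (65.9). D1 replicate 2 stood apart for mt-Co3 (585 CPM) and D7 replicates 2 and 4 for Btg2 (701) and Map3k6 (128). D28 replicates 2 and 3 did so for Klf2 (6178) and Alox12 (26.7). In microglia-like cells, No-TBI replicate 2 stood apart for Ifi27l2a (0.834 CPM), Lpl (27.5), Sphk1 (41.7) and Spp1 (19.7), and No-TBI replicate 3 for Apoc1 (0.154). In astrocyte-like cells it held for Il6 (2.49 CPM), Ptx3 (6.30) and Lcn2 (2.46) in No-TBI replicates 1, 2 and 3. It also held for Steap4 in D1 replicate 2 (162) and Lcn2 in D28 replicate 4 (242, others 3.47 to 6.33). In OPC-like cells it held for Gap43 in No-TBI replicate 2 (24.5 CPM), Agmo (3.35) and Fkbp5 (46.8) in D7 replicate 4 and Adm in D28 replicate 4 (8.62). In neutrophil-like cells it held for Chil3 in D1 replicate 4 (94.6 CPM) and Nos2 in D28 replicate 2 (22.8). With 0 CPM in the others, Apoc1, Nos2 and No-TBI Il6, Ptx3 and Lcn2 had to be flagged.

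Time points differed directly in 3448 endothelial genes between D7 and D1 and in 1680 between D28 and D7. The named genes of D7 with D1 (log2) were Iigp1 (2.20), Tgtp1 (2.01), Ifit3b (1.81), Ifit2 (1.74), Irf7 (1.74), Apln (-5.34), Lcn2 (-3.58), Pgf (-2.76), Igfbp3 (-1.82) and Scgb3a1 (-1.66). Those of D28 with D7 were Egr1 (1.66), Fos (1.41), Klf2 (1.40), Lcn2 (1.37), Btg2 (1.29), Selp (-2.54), Igfbp4 (-1.67), Emp1 (-1.51), Ifit3b (-1.47) and Irf7 (-1.47). By edgeR's quasi-likelihood test, shares at D7 were above those at D1 (log2 ratio) for OPC-like (1.46), microglia-like (1.15), T/NK-like (0.86) and neuroblast-like cells (0.56, lost in most settings, with adjusted p up to 0.595), and below for neutrophil-like (-6.90), astrocyte-like (-1.90), monocyte/macrophage-like (-1.86), ependymal-like (-0.71), endothelial-like (-0.57) and mural-like cells (-0.45). Shares at D28 were above those at D7 for neutrophil-like (4.37), T/NK-like (0.81), astrocyte-like (0.52) and microglia-like cells (0.26), and below for dendritic-like (-1.24), OPC-like (-0.92), neuroblast-like (-0.83), ependymal-like (-0.59) and mural-like cells (-0.37). None passed the permutation test, and other settings lost astrocyte, microglia, mural and ependymal calls (adjusted p up to 0.0997, 0.567, 0.546 and 0.0623). Outside the compared classes, cluster 15, which mixed microglial and endothelial markers, held 5.59% of cells at D7 and 0.265% in No-TBI, and cluster 27, led by interferon genes such as Cxcl10 and Ifit2, 2.36% and 0.155%.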

How the results depend on the processing

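Adding unnamed clusters to their leading class, and every setting of the OPC-like, T/NK-like and neutrophil-like classes, were chosen only after the results were seen. For the results that changed, the cause was not tested.

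Median-of-ratios scaling and Leiden resolution 2 moved no count of genes by over 1.5 times. Thinned to the smallest library, endothelial-like cells gave 2026, 1661 and 1537 genes for D1, D7 and D28 with No-TBI, 1388 for D7 with D1 and 636 for D28 with D7. Mural-like cells gave 989, 651 and 225, microglia-like cells 4176 at D7 and 3120 at D28, astrocyte-like cells 163, 469 and 15, OPC-like cells 195, 81 and 20, T/NK-like cells 4 and neutrophil-like cells 22. With doublets kept, mural-like cells gave 2501, 1719 and 983 genes, OPC-like cells 1564 at D7 and 470 at D28, and neutrophil-like cells 1018. With unnamed clusters added, mural-like cells at D28 gave 1185. Without the filter on low counts, astrocyte-like cells at D28 gave 277 and T/NK-like cells 570. The DESeq2 Wald test gave 216 for T/NK-like cells, and a minimum of 1000 UMIs gave 334 for neutrophil-like cells. OPC-like cells at D28 gave 486 with 2 groups in the fit and 413 with genes over 5 times higher in another class left out.

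The replicate number as a block gave 659 genes for mural-like cells at D28 in place of 417, and moved no other count of genes by over 1.5 times. In the other comparisons of endothelial-like, mural-like, microglia-like and astrocyte-like cells with No-TBI, not every pair had a correlation over 0.1, and 0 to 3 of 4 libraries correlated best with their own number. Endothelial-like cells at D28 came nearest, with 3 of 4 pairs over 0.1 (highest 0.165) and 3 best with their own, as many as mural-like cells at D1. The other classes were not checked.

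Leaving out 1 library at a time gave 693 to 1165 genes for mural-like cells at D7 and 231 to 547 at D28, 79 to 190 for astrocyte-like cells at D28, and 1027 to 1773, 631 to 1065 and 125 to 324 for OPC-like cells at D1, D7 and D28. It gave 199 to 410 for T/NK-like cells and 445 to 712 for neutrophil-like cells. The lowest values came without D7 replicate 1, D28 replicate 4, No-TBI replicate 3, D1 replicate 2, D7 replicate 3, D28 replicate 2, D28 replicate 3 and D28 replicate 4. Counts also moved by over 1.5 times for mural-like cells at D28 without D28 replicate 1 (265), 2 (264) or 3 (271) or No-TBI replicate 4 (262), for astrocyte-like cells at D28 without D28 replicate 2 or No-TBI replicate 1 (86 each), for OPC-like cells at D28 without D28 replicate 3 (160) and for T/NK-like cells without D7 replicate 1 (216) or 3 (227).

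Gene lists depended most on the test. With an estimated correlation no endothelial list passed at D1 or D28 (0 in place of 5 each), and 23 in place of 59 passed in mural-like, microglia-like and astrocyte-like cells. With fry, which asks only whether a list moves one way, 16, 13 and 15 endothelial lists passed at D1, D7 and D28. Lists turned direction, even some that passed. For endothelial junctions at D7 (adjusted p = 0.916) this held with the block (0.947) or genes left out (0.957), and without 1 library it was 0.686 to 0.997. For mural-like cells, leaving out 1 library gave 0.468 to 0.946 for contractile genes at D1 and 0.0391 to 0.914 for pericyte genes at D28, and contractile genes at D28 turned down with unnamed clusters added (adjusted p = 0.175). Immediate-early and heat-shock genes of astrocyte-like cells at D28 ranged from 4.5e-05 to 0.942 and turned up without No-TBI replicate 3.

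Among single genes, as log2 changes, Tnfaip3 in endothelial-like cells at D1 was -0.0309 with doublets kept (0.43 otherwise) and Mcm2 at D7 -0.0565 when thinned (0.36). In mural-like cells Gpx1 at D1 was -0.29 with unnamed clusters added (0.31), and with a minimum of 1000 UMIs Slc19a1 was -0.15 (0.27) and Pdgfrb -0.0523 (0.29) at D7. Cox5b in astrocyte-like cells at D1 was -0.20 when thinned (0.61), and Hk2 in OPC-like cells at D7 was 0.23 with doublets kept (-1.39).

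With brain-resident cells as the denominator only 8 of 12 classes are tested: 6 changed share at D1 and 5 at D28, the same classes that passed among these 8 before. With the exact permutation test 0 in place of 9 classes passed in D28 with D7, where 6 had an unadjusted p of 0.0286, the smallest possible, and 0.0571 after adjustment. Neuroblast-like cells in D7 with No-TBI and in D7 with D1 did not pass it either (adjusted p = 0.171 each), so that 11 share results were lost.

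Other share results also depended on the setting (adjusted p). In D7 with D1 the neuroblast share passed narrowly and did not pass with a minimum of 1000 UMIs (0.595), Leiden resolution 2 (0.0510), unnamed clusters added (0.0548), brain-resident cells as the denominator (0.272), or without any 1 library (0.0568 to 0.152) other than D1 replicate 2, D7 replicate 1, D28 replicate 1 or D28 replicate 3. In D28 with D7 the astrocyte share did not pass with a minimum of 1000 UMIs (0.0594), the block (0.0639), or without D7 replicates 2 (0.0607), 3 (0.0997) or 4 (0.0907) or D28 replicates 2 (0.0759) or 4 (0.0619). The ependymal share did not pass without D7 replicate 1 (0.0539) or D28 replicates 1 (0.0581) or 2 (0.0623), nor the microglia and mural shares with a minimum of 1000 UMIs (0.129 and 0.546) or unnamed clusters added (0.567 and 0.137). The ependymal share at D28 with No-TBI passed only without D28 replicate 1 (0.0194) or No-TBI replicate 2 (0.0255).

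Shares near no change turned direction (log2 ratio). Mural-like cells at D1 were at 0.0487 with a minimum of 1000 UMIs and 0.24 over brain-resident cells, and between -0.14 and 0.0302 without 1 library. Monocyte/macrophage-like cells at D7 were at 0.0483 with doublets kept, 0.41 with a minimum of 1000 UMIs (adjusted p = 0.015), 0.0172 at Leiden resolution 2 and 0.00022 with the block, and between -0.14 and 0.13 without 1 library. At D28 they were at 0.20 with a minimum of 1000 UMIs and between -0.0867 and 0.0248 without 1 library. Neuroblast-like cells at D28 were at 0.0802 with doublets kept and between -0.22 and 0.0626 without 1 library. Endothelial-like cells in D28 with D7 were at 0.0304 with doublets kept and 0.30 with a minimum of 1000 UMIs (adjusted p = 0.0043), and between -0.0751 and 0.0016 without 1 library.

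Of 217 list results, 101 passed in no setting (lowest adjusted p 0.0532), and of 60 share results 4 did. Thinning lowered the counts of genes by the largest factors in astrocyte-like, OPC-like, T/NK-like and neutrophil-like cells.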

Other observations

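The splits of libraries for the lists of OPC-like, T/NK-like and neutrophil-like cells, and for both endothelial results at D1, were written down only after the results were seen, and the glucocorticoid list was chosen after other falls had been seen.

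Dividing microglia-like cells, led by Top2a and Mki67, formed a cluster of 185 cells, 150 of them at D7.

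Zbtb16, which glucocorticoids induce, fell at D7 in endothelial-like, mural-like, astrocyte-like and OPC-like cells. Lower expression of glucocorticoid-induced genes may explain this. The median log2 change of 8 such genes in these 4 classes was -0.22 (SE 0.127 over genes, not libraries), with 3 of 29 values up and 12 down. The 8 went both ways and omit Fkbp5 and Tsc22d3, both lower in microglia-like cells, so this stays open.

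Other splits of the 8 libraries of each comparison into 4 and 4 were tested to measure chance, 35 with the real one. For genes, the real split alone (1 of 35) reached its count in all 19 comparisons. Chance can be excluded for each count alone, except mural-like cells at D1. The highest other splits gave 119, 1, 0, 12 and 0 genes in endothelial-like cells (D1, D7 and D28 with No-TBI, D7 with D1, D28 with D7), where the real ones gave 4367, 3787, 3651, 3448 and 1680. For D1, D7 and D28 with No-TBI they gave 44, 1 and 0 in mural-like cells (real 1659, 1130 and 417), 1, 0 and 2 in microglia-like cells (real 8126, 7310 and 6078), 61, 989 and 1 in astrocyte-like cells (real 1800, 3744 and 158) and 62, 12 and 1 in OPC-like cells (real 1732, 978 and 243). They gave 2 in T/NK-like cells (real 361) and 2 in neutrophil-like cells (real 670). In mural-like cells at D1 only 8 splits part all 4 same-numbered pairs, too few to exclude chance. The highest other gave 1 gene and 6 lists (44 and 8 with fewer pairs parted).

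For the number of lists that passed, chance can be excluded at most for mural-like cells at D28 taken alone, where 1 of 35 splits reached 8 lists and the highest other gave 7. That is the only such result among 19 comparisons, and none of the 8 lists passed with an estimated correlation. Chance could not be excluded elsewhere. In endothelial-like cells 10, 17, 5, 9 and 2 of 35 splits gave as many lists as the real 5, 4, 5, 6 and 10, with highest others of 10, 7, 7, 9 and 10. For D1, D7 and D28 with No-TBI, the splits that gave as many were 14, 13 and 6 in microglia-like cells (real 5, 9 and 8, highest other 7, 9 and 8), 6, 5 and 14 in astrocyte-like cells (real 7, 9 and 3, highest other 7, 9 and 7) and 14, 9 and 7 in OPC-like cells (real 5, 6 and 5, highest other 6 each). They were 12 and 14 in mural-like cells at D1 and D7 (real 5 each, highest other 8 and 6), 6 in T/NK-like cells (real 4, highest other 6) and 3 in neutrophil-like cells (real 3, highest other 3).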
